A study of Mus musculus with 9 samples.

How the data were processed

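Total RNA was taken from MOV10-knockout N2A cells 24 hours after transfection with WT, S970A or S970D MOV10, and libraries were made with a stranded poly(A) kit and sequenced for 101 cycles from each end on 1 NovaSeq lane, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20, Salmon 1.1.0, R 3.6.3 and the genome build GRCm38, with no order or role. The authors deposited 1 table of log2 CPM, the log2 of counts scaled to a common library total, for 15977 genes, 1 column per library, with replicates not pooled. The tool that made the log2 values, the prior count, the scaling and the filter on low genes are not given in the sources used here. The table shows an equal lowest value of -4.09 in all 9 columns, reached by 50 to 93 genes per library. The values turned back to CPM sum to between 955214 and 1069215 per library, so they were not scaled to a common total. The sums were 1014839 to 1069215 in the S970D libraries and S970A replicate 1, and 955214 to 981473 in the others. The steps between low values were not whole multiples of 1 read, so no read counts were recovered and the depth and its precision are unknown. A fold change of a gene near the lowest value is understated, because a prior count is part of the deposited log2 value. Other columns of the deposited table give a cluster colour and a row order for part of the genes, by a rule not given in the sources used here. No column of per-sample values was left unused.

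Groups and replicate numbers came from the labels. Every gene of the table entered the fits. For each comparison, limma 3.58.1 in R 4.3.3 was run on the deposited log2 values of all 9 libraries with the group as the only term, with 6 residual degrees of freedom, moderated variances with an intensity trend, two-sided p-values and Benjamini-Hochberg adjustment over all genes. A gene passed at an adjusted p under 0.05. A moderated F test asked for any difference among the 3 groups. The test, the samples and the alternatives were fixed before the data were examined, as were 32 gene lists of pathways, signs of RNA quality and markers of other cell types. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Beside each list stand counts of members that passed over all genes and adjusted over the list alone. List members were matched by the deposited symbol, then by the GENCODE vM21 symbol of the same gene ID.

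The genes named in the text followed a rule fixed before the data were examined. Mov10 came first. Per comparison, genes that passed, whose groups did not overlap and whose symbol is not a predicted model were named, up to 10 with the largest rise and 10 with the largest fall. Where fewer than 5 qualified in a direction, the genes with the smallest p in that direction filled it to 5. For a list called by camera, up to 4 members with the largest moderated test statistic in its direction were named, for other lists up to 2, and for the F test the 5 genes with the smallest p.

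Replicate numbers in the labels are shared by the groups, and no label says what a number marks. Deviations from the group means of same-numbered libraries correlated at 0.31, 0.11 and 0.16 for S970D with WT, all over 0.1, so the numbers were taken as pairs in that comparison. Of the 9 libraries, 6 correlated best with a library of their own number. Genes vary together, so such correlations across genes do not establish that the numbers mark pairs. The deviations correlated at 0.59, 0.07 and 0.49 for S970A with WT, and at 0.38, 0.00 and 0.24 for S970D with S970A, which does not meet the bound of 0.1. Fits with the replicate number as a block are therefore given beside S970D against WT, and beside the F test where the count moved. These fits held all 9 libraries, so they also take the numbers as pairs for S970A, which was not shown.

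Transcript lengths, GC content, untranslated regions and coordinates came from the GENCODE vM21 annotation of GRCm38. Of the gene IDs, 15959 (99.9%) were found there, and 15568 (97.4%) with the same version. For each gene the transcript with the longest coding sequence was used. The trend over GC content and length was removed per library, in an alternative chosen after the data were seen, with splines of 5 degrees of freedom for each property, fitted to the differences from the gene means. The other alternatives were a pseudocount of 1 on the CPM scale, a filter at a mean log2 CPM of 1, quantile normalization, median centring, only the 6 libraries of a comparison, other variance priors, each library left out, and, added after the data were seen, Mov10 as a covariate, S970A replicate 1 and WT replicate 1 both left out, the 3 libraries numbered 1 left out, and the trend removal joined to the block or to leaving out S970A replicate 1.

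The fits were tested on simulated data with the means and spreads of the 15977 genes of which 100 were changed by 1 and 100 by 2 on the log2 scale. In the simulation of S970D against WT, 46.0% of genes changed by 1 on the log2 scale and 90.0% of those changed by 2 were recovered. For S970A against WT, 45.0% and 76.0% were recovered, and for S970D against S970A 56.0% and 79.0%. With the spread of the first component taken out, 88.0% and 98.0% were recovered for S970D against WT, 83.0% and 97.0% for S970A against WT, and 81.0% and 100% for S970D against S970A. From 6 to 14 unchanged genes were called in each simulation. Genes were simulated as independent of each other, while in the real libraries the first component held 64.0% of the variance. The shares and false calls may therefore not hold for the real fits. Each share came from 1 draw of 100 genes, so differences between the comparisons may come from the draw.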

Results

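Messenger RNA levels were measured by RNA sequencing in N2A cells, a mouse neuroblastoma line, in which the gene for the RNA helicase MOV10 had been knocked out. The cells were transfected with 2 micrograms of DNA for 1 of 3 forms of MOV10 and harvested after 24 hours. WT is the unaltered protein. S970A carries alanine in place of serine 970, a residue that cannot be phosphorylated, and S970D carries aspartate there, whose negative charge stands in for a phosphate. Each form had 3 libraries, 9 in all, and no untransfected library was analysed here. The deposited table held 15977 genes as log2 CPM, the log2 of read counts scaled to a common library total. It carried no read counts, so the depth of each library is unknown. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries.

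The cells lack their own MOV10, and the labels do not give the species of the transfected DNA. Mov10 was the most abundant transcript of the table in each of the 9 libraries. The gene (ENSMUSG00000002227.15, a protein-coding gene on the minus strand of chromosome 3, 104794836 to 104818563 of GRCm38) reached 15.37 ± 0.41 log2 CPM with WT, 15.09 ± 0.42 with S970A and 14.72 ± 0.14 with S970D (mean ± SD, n = 3). It took from 2.28% of the summed CPM in S970D replicate 1 to 5.45% in WT replicate 3. The difference between S970D and WT was -0.65 ± 0.29 (SE) on the log2 scale, a ratio of 0.637, and each S970D library lay below each WT library. That difference did not pass the test across all genes (limma adjusted p = 0.111), and passed with the replicate number as a block (limma adjusted p = 0.0323). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. S970A differed from WT by -0.28 ± 0.29 (limma adjusted p = 0.776) and S970D from S970A by -0.37 ± 0.29 (limma adjusted p = 0.445), both within the spread of the replicates.

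The first principal component of the 9 libraries, computed without Mov10, held 64.0% of the variance. S970D replicates 1, 2 and 3 scored 0.44, 0.31 and 0.25 on it, and WT replicates 1, 2 and 3 scored -0.04, -0.36 and -0.46. S970A was divided: replicate 1 scored 0.40, among the S970D libraries, and replicates 2 and 3 scored -0.22 and -0.33, among the WT libraries. The median absolute log2 difference between replicates was 0.55 and 0.63 for the pairs that include S970A replicate 1, and from 0.13 to 0.38 for the other replicate pairs.

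**Figure D1:**
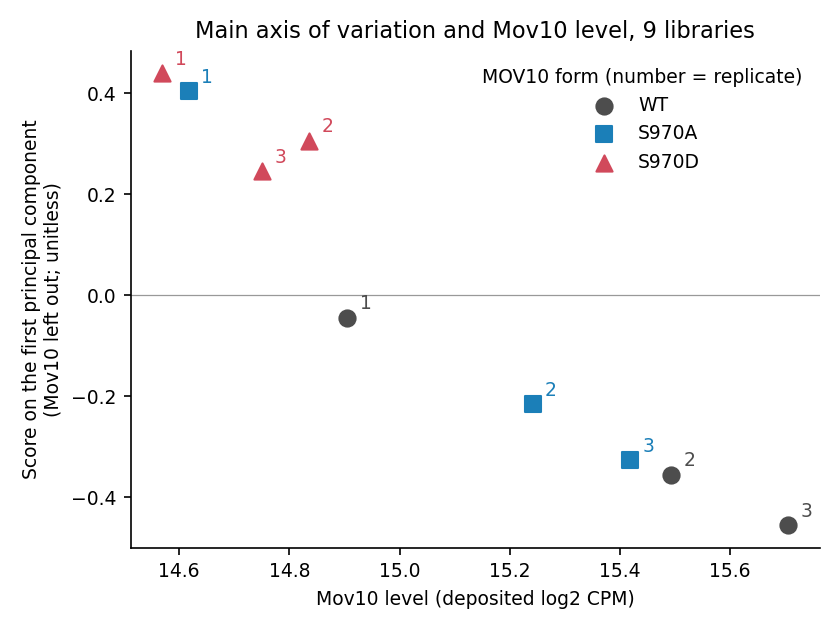
Score of each library on the first principal component (vertical, unitless, Mov10 left out) against its Mov10 level (horizontal, deposited log2 CPM), with colours and shapes for the MOV10 form and the replicate number beside each point. The 3 S970D libraries and S970A replicate 1 have scores from 0.25 to 0.44 and the lowest Mov10 levels, 14.57 to 14.84.

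S970D against WT asks whether messenger RNA levels differ when serine 970 of MOV10 is replaced by a residue that mimics its phosphorylation. Cxcl1, which encodes a chemokine that attracts neutrophils, fell by 2.45 ± 0.23 (SE) on the log2 scale, from 3.93 ± 0.23 log2 CPM in WT to 1.48 ± 0.09 in S970D (mean ± SD, n = 3; limma adjusted p = 0.0390). It was the 1 gene that passed in the fit of all 9 libraries, and no gene passed as higher. In that fit 7081 genes had an unadjusted p under 0.05. At a limma adjusted p under 0.1 it gave 3084 genes higher and 3241 lower, so the count of 1 also rests on the threshold of 0.05. The call of Cxcl1 ended without any 1 of 6 libraries, WT replicates 2 and 3, S970A replicate 2 and S970D replicates 1, 2 and 3 (limma adjusted p from 0.0619 to 0.244), and its limma adjusted p ranged from 0.000241 to 0.244 over all alternatives. Differences of smaller size were widespread. The 2 groups did not overlap in 9133 genes, 57.2% of the table, where chance gives 10% on average. Genes vary together: the first component held 64.0% of the variance, and S970D and WT did not overlap on it either. An exact permutation test of that score gave p = 0.1, the smallest possible, so the share of 57.2% does not decide on chance. Short and GC-rich transcripts were higher in S970D and long and AT-rich ones lower: the median log2 fold change was 0.72 in the 1099 shortest coding genes and -0.60 in the 1098 longest. The same trend parted S970A replicate 1 from S970A replicates 2 and 3, with a Spearman rho of -0.544 with length and 0.520 with GC content, against -0.50 and 0.588 in S970D against WT. With the replicate number as a block, 3547 genes rose and 3729 fell, 7276 of 15977 in all. The block takes the numbers as pairs, which was not established. Without the block, 7615 genes passed when S970A replicate 1 was left out, and 6727 with only these 6 libraries. The higher count therefore need not come from pairing. Counts of list members with the block are to be read against the 7276 of 15977. The named genes below have limma adjusted p-values of 0.0756 or more without the block, except Cxcl1, and their errors are from the fit without the block. With the block the list members given with values in the paragraphs on lists of this comparison had limma adjusted p-values from 0.00642 to 0.0249, while Egr2 and Pmp22 of the Schwann and glial list and Rab25 of the epithelial list did not pass (0.0502 to 0.105). Of the members given with values, H2ac18, H4c9, Tnnt1, Tnni1, Tnnt3, Ddx5, Lin28b, Kif11, Ezh2, Ifih1, Parp9, Mphosph8 and Th no longer passed with the block once the trend over GC content and length was removed. Their limma adjusted p-values were then 0.0590 to 0.620, and those of the other members given with values 0.0142 to 0.0469.

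Among the genes with the smallest p, Rnaseh2c (ENSMUSG00000024925.11, chromosome 19, 5601873 to 5607019), a subunit of the nuclease that removes RNA from RNA-DNA hybrids, was at 5.39 ± 0.49 log2 CPM in S970D and 3.24 ± 0.30 in WT (mean ± SD, n = 3). The difference was 2.16 ± 0.32 (SE), with a limma adjusted p of 0.0756, and 0.00642 with the replicate block. Btbd16 was higher by 1.41, the vomeronasal receptor gene Vmn2r110 by 1.65, the neurexophilin gene Nxph4 by 1.92 and the chemokine receptor gene Cxcr5 by 1.18. On the lower side, Duxbl2 (ENSMUSG00000072675.12, chromosome 14, 26118349 to 26129763), a double homeobox gene, was at -3.46 ± 1.09 log2 CPM in S970D and 0.62 ± 0.45 in WT. Its S970D values include 2 libraries at the lowest value of the table, and its reads may be shared with near-identical copies, so its size is uncertain. Gng4, a G protein gamma subunit, was at 0.82 ± 0.29 log2 CPM in S970D and 3.82 ± 0.55 in WT, and Zfp874a (-1.46) and the myosin gene Myo5c (-1.12) were also lower. All 9 of these genes passed with the replicate block, with limma adjusted p-values from 0.00642 to 0.00771.

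Messenger RNAs of the cytosolic ribosomal proteins stood higher in S970D than in WT, with a median log2 fold change of 1.01 (0.66 with quantile normalization). Of 79 measured members, 78 were above 0. None passed over all genes, 67 were higher when adjusted over the list alone, and 71 rose with the replicate block. Rpl38 (1.68 ± 0.45, SE), Fau (1.64 ± 0.47), Rpl41 (1.56 ± 0.45) and Rps27 (1.30 ± 0.36) led the list. Nuclear genes for oxidative phosphorylation, the respiratory chain and ATP synthase, had a median of 0.86 over 74 members, of which 45 were higher and 1 lower when adjusted over the list alone, and 58 rose and 1 fell with the block. They were led by Ndufc1 (1.84 ± 0.50), Atp5e (1.77 ± 0.49), Ndufv3 (1.54 ± 0.42) and Cox5b (1.04 ± 0.29). Replication-dependent histone genes, whose messages mostly lack a poly(A) tail and are therefore a sign of library quality in poly(A)-selected RNA, had a median of 0.90. Of 40 members, 7 were higher when adjusted over the list alone and 20 rose with the block, among them H2ac18 (2.21 ± 0.62), H3c6 (2.14 ± 0.51), H3c3 (1.89 ± 0.50) and H4c9 (0.89 ± 0.23). The camera adjusted p was 1.53e-14 for the ribosomal proteins, 2.03e-11 for oxidative phosphorylation and 6.74e-06 for the histones. All 3 calls were lost with an estimated correlation (adjusted p = 0.643 with an estimated correlation). With the trend over GC content and length removed the medians were 0.50, 0.30 and 0.32, and the lists stayed called (camera adjusted p from 1.21e-11 to 0.0475), but these calls too were lost with an estimated correlation (adjusted p = 0.725 with an estimated correlation). The histone median was 0.57 with a mean log2 CPM of at least 1. These are short transcripts, with median lengths of 838, 849.5 and 579 bases against 2660 for all genes. Ribosomal protein and histone genes have near-identical copies or pseudogenes, so reads may be split among them.

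Genes of hypoxia and glycolysis had a median log2 fold change of 0.25 in S970D over 36 members (camera adjusted p = 0.0453; 0.143 with the replicate block, which ends the call). The call also ended with quantile normalization (0.165) and without WT replicate 1, any 1 of the S970A replicates, or S970D replicate 1 or 3 (camera adjusted p from 0.0540 to 0.435), with a median of 0.15 without WT replicate 1. Adjusted over the list alone, 10 were higher and none lower, led by the glycolytic enzymes Aldoc (1.52 ± 0.34, SE) and Pfkl (0.78 ± 0.20), the lactate transporter Slc16a3 (1.05 ± 0.24) and Ankrd37 (0.93 ± 0.19). Muscle markers had a median of 0.96 over the 10 measured of 20 listed (camera adjusted p = 0.0243; 0.0590 with quantile normalization), and 6 were higher when adjusted over the list alone. The calls of both lists were lost with an estimated correlation (adjusted p = 0.643 with an estimated correlation). The troponin genes Tnnt1 (1.16 ± 0.33), Tnni1 (0.97 ± 0.33) and Tnnt3 (0.95 ± 0.30) and the desmin gene Des (1.04 ± 0.33) led that list. Markers of other cell types were not called. Their medians were 0.48 for endothelial, 0.45 for macrophage and leukocyte, 0.22 for fibroblast, 0.01 for epithelial and -0.15 for Schwann and glial markers, with camera adjusted p-values from 0.289 to 0.771. The epithelial median turned to -0.01 under quantile normalization, and with the trend over GC content and length removed the macrophage median turned to -0.11 and the epithelial to -0.16.

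On the lower side, factors of the RNA-induced silencing complex and microRNA biogenesis had a median log2 fold change of -0.41 in S970D over 26 members (camera adjusted p = 0.0336; 0.0547 without WT replicate 1; 0.0777 with a mean log2 CPM of at least 1). Adjusted over the list alone, 5 were lower, and 9 fell with the replicate block. The list was led by Dgcr8, the partner of Drosha in microRNA processing (-0.84 ± 0.18, SE), the helicase gene Ddx5 (-0.69 ± 0.19), Lin28b, which blocks let-7 maturation (-1.04 ± 0.29), and Tnrc6a, the AGO-binding scaffold GW182 (-1.01 ± 0.29). Conserved targets of the let-7 microRNA had a median of -0.34 over 31 members (camera adjusted p = 0.00763), with 5 lower and 1 higher when adjusted over the list alone, and 11 lower and 1 higher with the block. Their leading members were Rdx (-1.24 ± 0.36), Lin28b, Ncoa3 (-0.71 ± 0.21) and Dna2 (-0.62 ± 0.15). Genes of the G2 and M phases had a median of -0.22 over 45 members (camera adjusted p = 0.0236; 0.0558 with a mean log2 CPM of at least 1), with 14 lower and 1 higher when adjusted over the list alone, and 19 lower and 4 higher with the block. Ect2 (-1.24 ± 0.35), Ccna2, which encodes cyclin A2 (-1.08 ± 0.26), the mitotic kinesin gene Kif11 (-0.80 ± 0.24) and Cdca2 (-0.71 ± 0.21) led it. These 3 calls were lost with an estimated correlation (adjusted p = 0.643 with an estimated correlation). Over all genes the block called 7276 of 15977, of which 3729 were lower. Counting both directions, the share of members called with the block was below that over all genes for silencing factors and let-7 targets. The share called lower was above that over all genes in each of the 3 lists.

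**Figure D2:**
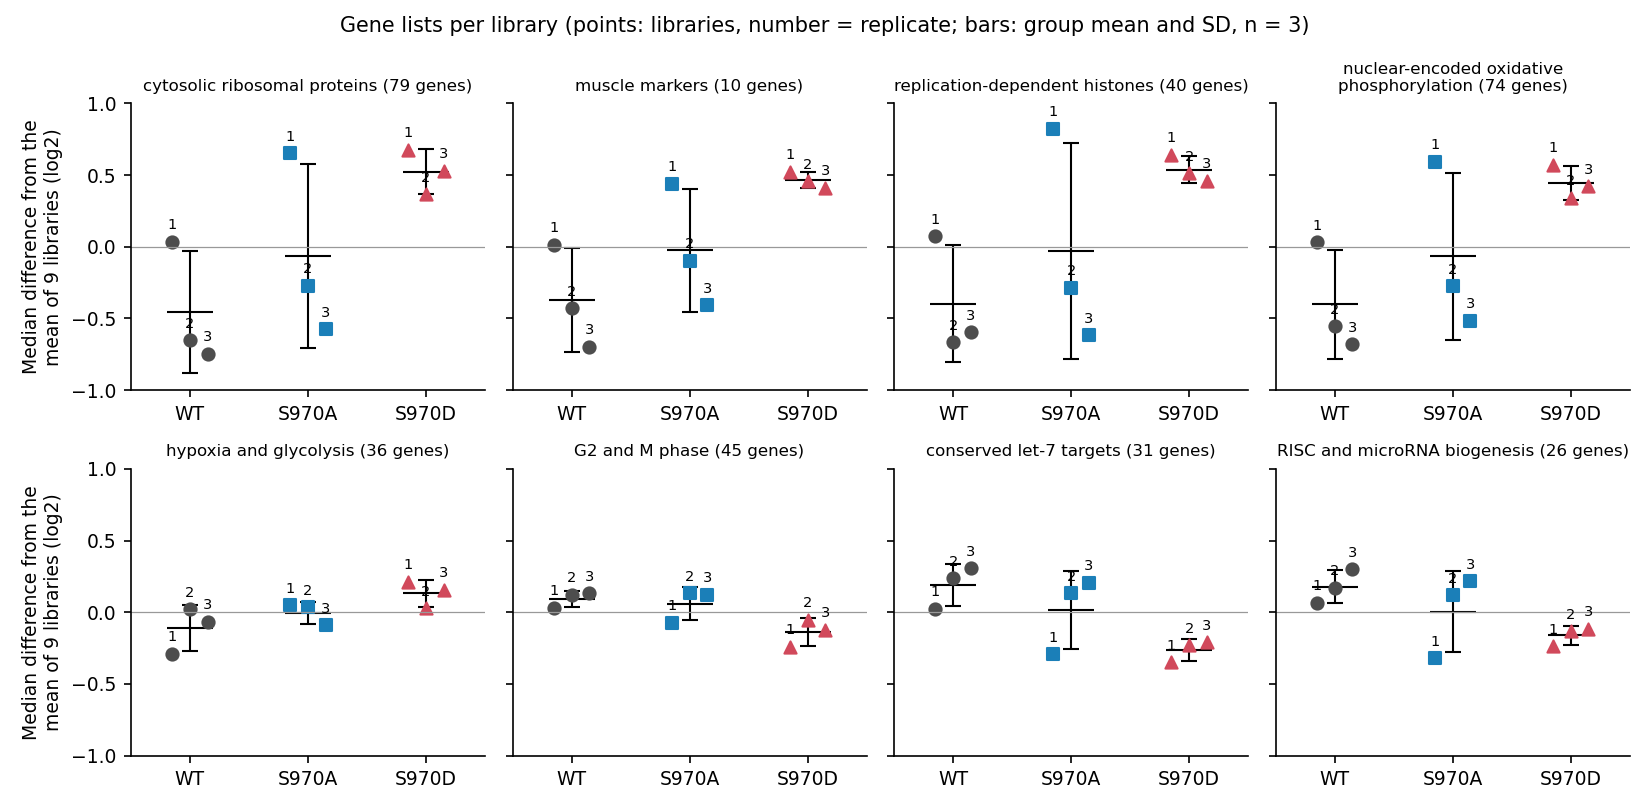
Median difference of each gene list from the mean of the 9 libraries (vertical, log2), per library, for the 8 lists called in S970D against WT, with points for libraries, replicate numbers beside them, and bars for the group mean and SD (n = 3). S970A replicate 1 lies with the S970D libraries in the ribosomal protein list, at 0.65 against 0.36 to 0.68, and S970A replicates 2 and 3 lie at -0.27 and -0.57.

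The other 24 lists were not called in S970D against WT, with camera adjusted p-values from 0.153 to 0.787. Targets of miR-124 had a median log2 fold change of -0.60 over 26 members, with 4 lower and 2 higher when adjusted over the list alone; the chromatin genes Ezh2 (-0.76 ± 0.17, SE) and Actl6a (-0.71 ± 0.18) were lower. Transcripts known to be substrates of nonsense-mediated decay had a median of 0.47, interferon-stimulated genes -0.32 and factors that control retroelements -0.31. In the interferon list the RNA sensor gene Ifih1 (-0.93 ± 0.24) and Parp9 (-0.64 ± 0.17) had the largest test statistics, and in the retroelement list Rnaseh2c and Mphosph8 (-0.77 ± 0.20). Retroelement factors went both ways, with 8 higher and 11 lower when adjusted over the list alone. By that count 7 genes of the S phase were lower and 1 higher, 4 nonsense-mediated decay factors were lower and 2 higher, 3 endothelial and 2 macrophage markers were higher, and 3 genes of NF-kappaB and inflammation were lower. Mitochondrially encoded messenger RNAs had a median of -0.30, with mt-Co3 at 0.63 ± 0.20 and mt-Co1 at -1.23 ± 0.49. Neuronal genes went both ways around a median of 0.10: Eno2, neuron-specific enolase, was higher by 1.00 ± 0.20 and the synapsin gene Syn1 by 0.73 ± 0.17. Among catecholamine genes, with a median of 0.13, Th, the rate-limiting enzyme of catecholamine synthesis (1.30 ± 0.27), and its regulator Hand2 (1.02 ± 0.29) were higher. Genes of NF-kappaB and inflammation had a median of -0.23, and besides Cxcl1 the cytokine gene Il6 was lower by a log2 fold change of -1.29 ± 0.25. Medians were -0.24 for cholesterol synthesis, -0.18 for p53 targets, -0.17 for axon guidance, 0.19 for NRF2 targets, 0.10 for the S phase and 0.04 for the unfolded protein response. They lay between -0.11 and 0.15 for messenger RNA decay, nonsense-mediated decay factors, ATF4 targets, heat shock and immediate early genes. The sign of each of those 5 medians changed under quantile normalization or median centring, and for heat shock and ATF4 targets the median and the camera test differed in sign. With the trend over GC content and length removed, the median turned to 0.011 for retroelement factors, 0.012 for cholesterol synthesis, 0.085 for messenger RNA decay, 0.091 for nonsense-mediated decay factors and -0.028 for heat shock, and that of mitochondrially encoded messenger RNAs was -0.014. Median centring moved the median of all genes by 0.11 in this comparison.

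**Figure D3:**
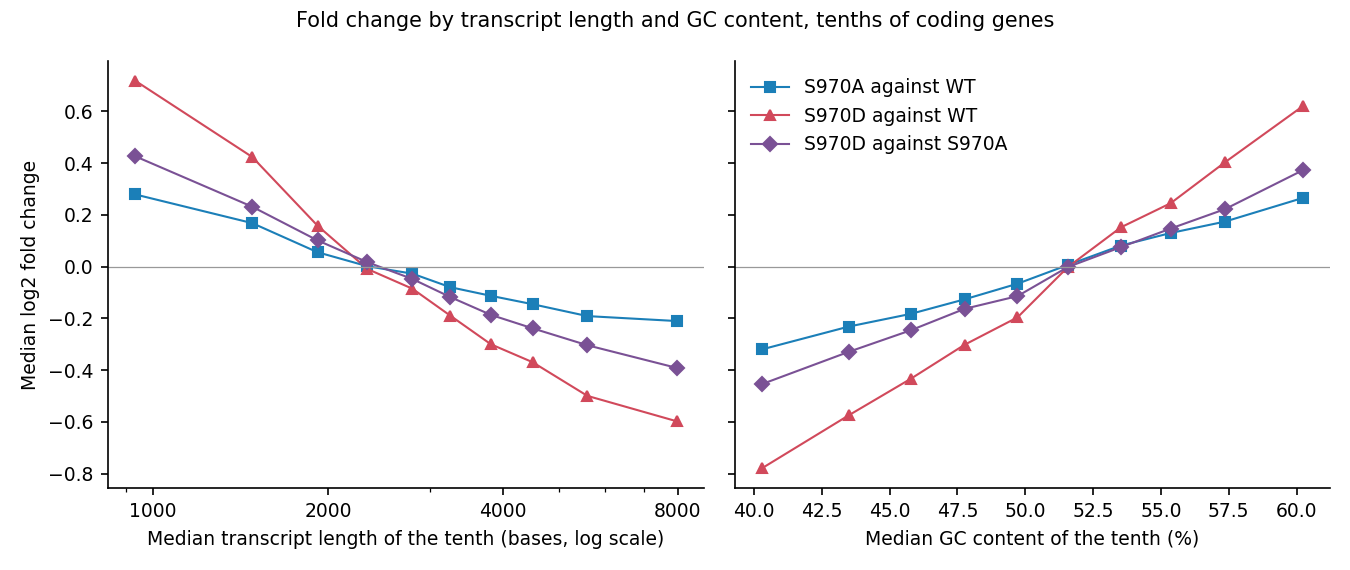
Median log2 fold change (vertical) of 10981 coding genes in 10 bins of equal size by transcript length (left, bases, log axis) and by GC content (right, percent), each point 1 bin of 1096 to 1099 genes, with a line for each comparison. In S970D against WT the median goes from 0.72 to -0.60 with length, and from -0.78 to 0.62 with GC content.

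Genes were tested with limma on the log2 CPM of all 9 libraries. The count of genes changed rested on the libraries in the fit and on the threshold. It was 1 with all 9 (6325 at an adjusted p under 0.1), 6727 with the 6 libraries of these groups, and 7615 without S970A replicate 1. That library belongs to neither group but widens the shared spread. With the trend over GC content and length removed from each library, the count was 0 without the replicate block and 3968 with the block, and 4 list calls ended. The median of let-7 targets went from -0.34 to -0.27 (camera adjusted p = 0.0822), of silencing factors from -0.41 to -0.10 (0.440), of the G2 and M phases from -0.22 to -0.10 (0.364) and of muscle markers from 0.96 to 0.34 (0.147).

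S970A against WT asks whether messenger RNA levels differ when serine 970 cannot be phosphorylated. No gene passed (limma), and 280 genes had an unadjusted p under 0.05, where 799 would by chance. The 2 groups did not overlap in 1025 genes, 6.42% of the table, where chance gives 10% on average. Genes with the smallest p on the higher side included Kctd15 (0.82 ± 0.20, SE), Vmn2r110 (1.00 ± 0.27) and the ribosomal pseudogenes Rpl15-ps2 (1.27 ± 0.35) and Rps10-ps2 (2.40 ± 0.68). Those on the lower side were Gng4 (-1.94 ± 0.51), Cxcl1 (-0.90 ± 0.23), the pseudogene Kansl2-ps (-3.62 ± 0.97, with 5 libraries at the lowest value of the table), Eogt (-1.02 ± 0.28) and the interferon regulatory factor gene Irf2 (-0.47 ± 0.13). Each had a limma adjusted p of 0.776. Reads of the 3 pseudogenes may come from their parent genes.

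By camera, 6 of the 32 lists were called in S970A against WT. The ribosomal protein list had a median log2 fold change of 0.39 with 76 of 79 members above 0 (camera adjusted p = 4.64e-10), oxidative phosphorylation 0.34 with 69 of 74 (2.55e-08) and the replication-dependent histones 0.40 with 35 of 40 (0.000151). Their leading members included Rpl27 (1.18 ± 0.75, SE), Rpl38 (0.74 ± 0.45), Rpl41 (0.68 ± 0.45) and the ribosomal laminin receptor gene Rpsa (0.52 ± 0.34). In oxidative phosphorylation they were Atp5e (0.81 ± 0.49), Cox5b (0.45 ± 0.29), Ndufa7 (0.43 ± 0.25) and Ndufb3 (0.38 ± 0.23), and among the histones H2bc12 (1.41 ± 0.74), H3c6 (1.35 ± 0.51), H2ac18 (1.14 ± 0.62) and H1f1 (0.98 ± 0.48). Without S970A replicate 1 these 3 medians were 0.029, 0.012 and 0.027 and the calls ended (camera adjusted p = 0.965 for each). Without all 3 libraries numbered 1, an alternative chosen after the data were seen, they were 0.27, 0.20 and 0.30, and the lists stayed called (camera adjusted p from 2.70e-13 to 0.0124). The medians were 0.24, 0.21 and 0.23 without WT replicate 3 and 0.66, 0.58 and 0.61 without S970A replicate 3, and without WT replicate 1 the first 2 were 0.63 and 0.57. These lists stayed called in each case (camera adjusted p from 6.91e-16 to 0.000973). With the trend over GC content and length removed the first 2 were 0.19 and 0.13, still called (1.03e-06 and 0.000152; adjusted p = 0.775 with an estimated correlation). Interferon-stimulated genes had a median of -0.19 over 48 members (camera adjusted p = 0.0243). The RNA sensor genes Ddx58 (-0.56 ± 0.25) and Ifih1 (-0.47 ± 0.24), with Rtp4 (-0.69 ± 0.36) and Xaf1 (-0.34 ± 0.16), led it. Hypoxia and glycolysis had a median of 0.12 (camera adjusted p = 0.0436), led by Aldoc (1.03 ± 0.34), Slc16a3 (0.51 ± 0.24), Ankrd37 (0.45 ± 0.19) and Pgk1 (0.37 ± 0.14). Muscle markers had a median of 0.36 (camera adjusted p = 0.0436), led by Tnni1 (0.64 ± 0.33), Cav3 (0.54 ± 0.43), Tnnt1 (0.44 ± 0.33) and Des (0.43 ± 0.33). No member of the 6 lists passed over all genes or when adjusted over the list alone. Each call was lost with an estimated correlation (adjusted p = 0.727 with an estimated correlation).

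The other 26 lists were not called in S970A against WT, with camera adjusted p-values from 0.0651 to 0.943. Silencing factors had a median log2 fold change of -0.18, let-7 targets -0.19, miR-124 targets -0.30 and G2 and M phase genes -0.09. Mitochondrially encoded messenger RNAs had a median of -0.13, and the 5 lists of markers of other cell types besides muscle lay between -0.12 and 0.12. With a mean log2 CPM of at least 1, or without S970A replicate 2, 3 lists were called, and 2 without S970A replicate 1. The calls of interferon-stimulated genes and of hypoxia and glycolysis ended without WT replicate 1, S970A replicate 2 or S970A replicate 3 (camera adjusted p from 0.0837 to 0.922), and that of muscle markers without any 1 of 6 libraries (0.0537 to 0.390), WT replicates 2 and 3, S970A replicates 1 and 2 and S970D replicates 1 and 2. The interferon median was -0.078 without S970A replicate 1, -0.31 without S970A replicate 3 and -0.10 with the trend over GC content and length removed. Its call also ended with a mean log2 CPM of at least 1 (0.148) and without the libraries numbered 1 (median -0.050, 0.751). The muscle median was 0.091 without S970A replicate 1, 0.54 without WT replicate 1 and 0.63 without S970A replicate 3. Its call ended with quantile normalization (0.0836), with a mean log2 CPM of at least 1 (0.0642) and without the libraries numbered 1 (0.104). The hypoxia and glycolysis median turned to -0.0062 without WT replicate 1, and its call ended with quantile normalization (median 0.065, 0.0941). The histone call ended with the trend over GC content and length removed (median 0.18, camera adjusted p = 0.140) and with a mean log2 CPM of at least 1 (0.0642), and the muscle call with the trend removed (median 0.18, 0.221).

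S970D against S970A compares the charged with the uncharged residue. No gene passed (limma), and 1110 genes had an unadjusted p under 0.05. The 2 groups did not overlap in 1289 genes, 8.07% of the table, where chance gives 10% on average. The smallest p-values on the higher side were those of Uba7, which encodes the enzyme that activates the ubiquitin-like protein ISG15 (1.66 ± 0.22, SE), Rnaseh2c (2.09 ± 0.32), Asb2 (1.37 ± 0.23), Gpr45 (1.07 ± 0.19) and Cxcr5 (1.02 ± 0.20). On the lower side they were those of Duxbl2 (-3.78 ± 0.51), Cxcl1 (-1.55 ± 0.23), Myo5c (-1.13 ± 0.21), the actin pseudogene Actg-ps1 (-1.29 ± 0.28) and Ptar1 (-0.74 ± 0.17). Their limma adjusted p-values lay from 0.298 to 0.411.

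By camera, 5 lists were called in S970D against S970A. Ribosomal proteins had a median log2 fold change of 0.60 (camera adjusted p = 1.53e-13; median 0.38 with quantile normalization), led by Rpl29 (1.20 ± 0.53, SE), Rpl28 (0.97 ± 0.43), Rpl7 (0.94 ± 0.33) and Rps27 (0.78 ± 0.36). Oxidative phosphorylation had a median of 0.49 (2.98e-10), led by Ndufc1 (1.15 ± 0.50), Ndufv3 (0.95 ± 0.42), Ndufa5 (0.89 ± 0.43) and Cox4i1 (0.68 ± 0.31). The replication-dependent histones had a median of 0.61 (7.66e-05), led by H3c1 (1.57 ± 0.55), H3c3 (1.14 ± 0.50), H3c8 (0.74 ± 0.37) and H4c9 (0.61 ± 0.23). Targets of let-7 had a median of -0.27 (0.00711), with Lin28b (-0.61 ± 0.29), Igf2bp2 (-0.49 ± 0.19), Ncoa3 (-0.48 ± 0.21) and Dna2 (-0.34 ± 0.15) in the lead. Genes of the G2 and M phases had a median of -0.20 (0.00711), with Ccna2 (-0.73 ± 0.26), Bub1b (-0.58 ± 0.24), Ckap5 (-0.51 ± 0.20) and Ttk (-0.47 ± 0.19). No member of these lists passed over all genes or when adjusted over the list alone, and each call was lost with an estimated correlation (adjusted p = 0.828 with an estimated correlation). Of the other 27 lists, 3 had 1 member that passed when adjusted over the list alone: Rnaseh2c among retroelement factors, Cxcl1 in the NF-kappaB list and Cd68 among macrophage markers (1.23 ± 0.34).

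The comparison of S970D with S970A turned on S970A replicate 1. Without it, 2982 genes rose and 3325 fell, 6307 in all (limma), and the G2 and M phase call ended (median -0.31, camera adjusted p = 0.0620; 0.0525 without S970D replicate 1). The medians of ribosomal proteins, oxidative phosphorylation and histones were 0.96, 0.84 and 0.97 without S970A replicate 1 and 0.34, 0.27 and 0.31 without S970A replicate 3, and that of let-7 targets was -0.42 without S970A replicate 1 and -0.16 without S970A replicate 2 or S970D replicate 1. With the trend over GC content and length removed, the calls of let-7 targets, histones and G2 and M phase ended (camera adjusted p from 0.123 to 0.140), and the medians of ribosomal proteins and oxidative phosphorylation were 0.31 and 0.18. The histone median was 0.32 with a mean log2 CPM of at least 1.

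Over the 3 groups together, no gene passed the limma F test, and 3953 genes had an unadjusted p under 0.05. Cxcl1, Duxbl2, Uba7, Rnaseh2c and Btbd16 had the smallest p-values, with limma adjusted p-values of 0.132 for Cxcl1 and 0.202 for the other 4. Cxcl1 (chromosome 5, 90891241 to 90893115) was at 3.93 ± 0.23 log2 CPM in WT, 3.03 ± 0.45 in S970A and 1.48 ± 0.09 in S970D (mean ± SD, n = 3), and the 3 groups did not overlap. Btbd16 went the other way, at -0.87 ± 0.24, -0.28 ± 0.12 and 0.55 ± 0.05. Uba7 (chromosome 9, 107975505 to 107984060) was lowest in S970A, at 0.04 ± 0.12, between neither of the others, with WT at 0.79 ± 0.28 and S970D at 1.70 ± 0.24. Rnaseh2c and Duxbl2 had similar levels in WT and S970A, at 3.24 ± 0.30 and 3.30 ± 0.54 for Rnaseh2c and 0.62 ± 0.45 and 0.32 ± 0.16 for Duxbl2. The count of genes in this test was 4716 with the replicate block and 6558 without S970A replicate 1.

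**Figure D4:**
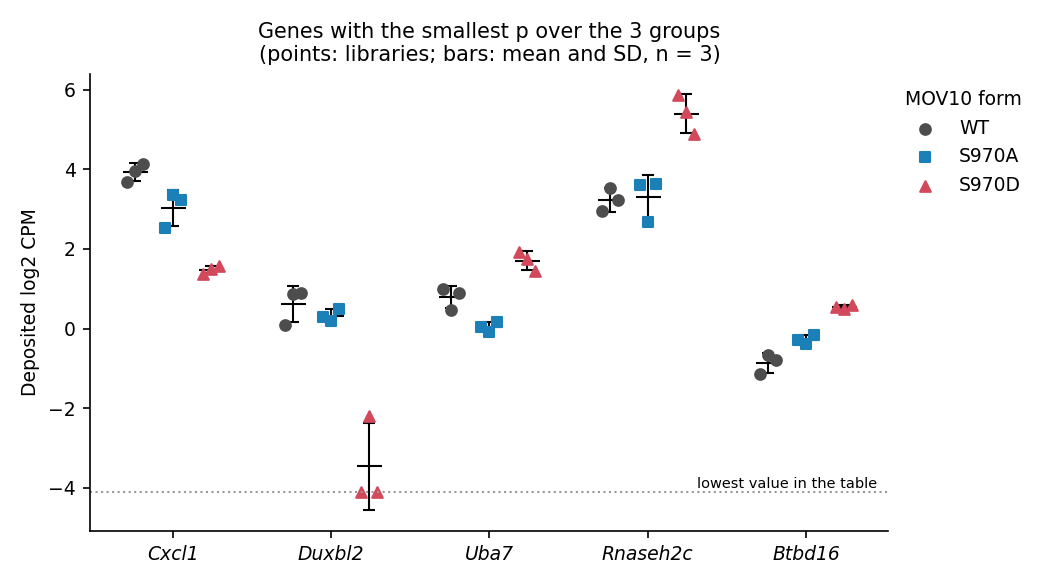
Deposited log2 CPM (vertical) of the 5 genes with the smallest p over the 3 groups, with points for libraries, colours and shapes for the MOV10 form, bars for the mean and SD (n = 3), and a dotted line at the lowest value of the table. Cxcl1 lies from 3.69 to 4.14 in WT and from 1.38 to 1.56 in S970D, and 2 of the 3 S970D values of Duxbl2 are at the lowest value.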

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

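The tests of GC content and length and the splits of the F test with the replicate block were chosen after the result was seen, and the list tests and the other splits of the libraries before.

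For 5 lists camera at its preset correlation of 0.01 called a difference between the effects of S970D and S970A against WT. This is the camera test of S970D against S970A, and none of the 5 was called with an estimated correlation. The medians of that difference were 0.60 for ribosomal proteins, 0.49 for oxidative phosphorylation, 0.61 for the replication-dependent histones, -0.27 for let-7 targets and -0.20 for the G2 and M phases, with camera adjusted p-values from 1.53e-13 to 0.00711 (adjusted p = 0.828 with an estimated correlation). With the trend over GC content and length removed, the calls of let-7 targets, histones and the G2 and M phases ended (camera adjusted p from 0.123 to 0.140). That of the G2 and M phases also ended without S970A replicate 1.

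Ribosomal protein and oxidative phosphorylation messages had median log2 fold changes of 1.01 and 0.86 in S970D against WT, and both lists hold short transcripts. After the trend over GC content and length was removed, the ribosomal protein median was 0.50 (quartiles 0.338 and 0.695) and the oxidative phosphorylation median 0.30 (0.108 and 0.593), and both lists stayed called (camera adjusted p = 1.21e-11 and 1.23e-06), but neither was called with an estimated correlation before the removal (adjusted p = 0.643 with an estimated correlation) or after it (adjusted p = 0.725 with an estimated correlation). The medians and quartiles stayed positive, and a part of each difference went with the trend. The quartiles are a spread over members that vary together (estimated correlations of 0.62 and 0.46 after the removal), not over libraries. They therefore do not decide whether the trend was the whole cause. S970A replicate 1, which carries the other residue, had a ribosomal protein median of 0.65 above the mean of all libraries, within the 0.36 to 0.68 of S970D, so a cause that is not the MOV10 form stays open beside the form itself. Reads shared between ribosomal protein genes and their pseudogenes were not tested.

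Other splits of the libraries were counted for each test of genes (limma). For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In S970D against WT, 2 of the 10 splits gave at least the real count of 1 gene, and the highest other split gave 2. The replicate numbers were taken as pairs in this comparison from correlations of 0.31, 0.11 and 0.16, though no label says so. With the replicate number as a block the real split gave 7276 genes, the 3 other splits that part all 3 pairs gave 0, and the 6 that part 1 pair gave 0 to 2. The blocked fit held all 9 libraries, and the numbers were not shown to pair those of S970A. Splits that part all 3 pairs are also too few for a share under 0.05, so this does not decide on chance. In S970A against WT all 10 splits gave at least the real count of 0, and the highest other gave 51 (11 with the replicate block). In S970D against S970A all 10 did so as well. The highest other, with S970A replicate 1 in the place of S970D replicate 3, gave 591, which points to a structure of the libraries apart from the groups. With the replicate block that split gave 1. In the F test, 100 of 100 splits drawn from 280 gave at least the real count of 0, as any split must, so this says nothing of chance. There the highest other split gave 3925 genes, with S970A replicate 1 and S970D replicates 1 and 2 in 1 group and WT whole, the same structure. With the replicate block the F test gave 4716 genes, and 1 of the 36 splits that put 1 library of each number in each group, the real one, gave as many. The numbers were not shown to pair the libraries of all groups, which these splits need, so this does not decide on chance. The highest other gave 3983, with S970A replicate 1 and S970D replicate 1 exchanged and WT whole.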

How the results depend on the processing

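The alternatives with the trend over GC content and length removed, with Mov10 as a covariate, with S970A replicate 1 and WT replicate 1 both left out, and with the 3 libraries numbered 1 left out were chosen after the result was seen. Over 268 named genes and called lists, 5081 values under an alternative kept direction and side of the threshold, 779 kept direction and came past it, 76 kept direction and no longer passed, and 30 changed direction. The cause was not tested, except that fewer libraries or another spread enter some fits by construction.

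In S970D against WT the count of genes, 1, was 7276 with the replicate block, 0 with log2(CPM + 1), 0 without the intensity trend, 6727 with only the 6 libraries of the comparison, 0 with the GC content and length trend removed, 3968 with that and the block, 8985 with S970A replicate 1 and WT replicate 1 both left out, 4155 with S970A replicate 1 left out and the trend removed, and 7854 with the 3 libraries numbered 1 left out. Leaving out each library gave 0 to 7615, the highest without S970A replicate 1. In S970D against S970A the count, 0, was 7580 with both left out, 2652 with S970A replicate 1 left out and the trend removed, 6106 without the libraries numbered 1, and 0 to 6307 over each library left out, the highest without S970A replicate 1. In S970A against WT it was 1 with both left out, 1 without the libraries numbered 1, and 0 to 1 over each library left out. The F test gave 4716 with the replicate block, 1251 with the trend removed and the block, 8261 with both left out, 2922 with S970A replicate 1 left out and the trend removed, and 0 to 6558 over each library left out.

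The count of lists fell to 0 in S970A against WT, 0 in S970D against WT and 0 in S970D against S970A with the correlation estimated from the data. In S970A against WT it was 3 with the replicate block, 3 with a mean log2 CPM of at least 1, and 2 to 6 over each library left out. It was 6 to 9 in S970D against WT over each library left out, and in S970D against S970A 4 to 7, with 3 after the trend was removed.

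Mov10 in S970D against WT passed with the replicate block (-0.65, limma adjusted p = 0.0323), with the trend removed and the block (-0.88), with both libraries left out (-0.88), with S970A replicate 1 left out and the trend removed (-0.88), and without the libraries numbered 1 (-0.81). In S970D against S970A it passed with both left out (-0.61). WT replicate 1 (14.90 log2 CPM) and S970A replicate 1 (14.62) had the lowest Mov10 levels of their groups. Leaving either out therefore widened the gap of its group to S970D by construction. Over each library left out the Mov10 difference was -0.88 to -0.48 in S970D against WT, -0.61 to -0.21 in S970D against S970A and -0.51 to -0.04 in S970A against WT. Quantile normalization gave no value for Mov10, which ranks first in each library and is set equal by it.

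These values changed direction, in some cases only without 1 library. In S970A against WT the list medians over each library left out went from 0.029 to 0.66 for ribosomal proteins, 0.012 to 0.58 for oxidative phosphorylation and 0.027 to 0.61 for histones, each lowest without S970A replicate 1, where the camera test pointed down. Without all 3 libraries numbered 1 they were 0.27, 0.20 and 0.30, and the lists stayed called, as they did with the replicate block (camera adjusted p = 6.02e-14, 5.67e-12 and 0.000160). The interferon (0.119), hypoxia and glycolysis (0.119) and muscle lists (0.0791) were not called with the block. Over each library left out mt-Nd4l went from -1.33 to 0.13 and Pmp22 from -0.27 to 0.14, both highest without S970A replicate 1. Mbp went from -0.36 to 0.067, highest without WT replicate 3 and 0.049 without S970A replicate 1, and Fcer1g from -0.99 to 0.14, highest without S970A replicate 3 and 0.12 without WT replicate 1. The hypoxia and glycolysis median in S970A against WT was -0.0062 without WT replicate 1 and -0.00063 without the libraries numbered 1, with the camera test not past its threshold. With S970A replicate 1 left out and the trend removed mt-Nd4l was 0.23, Pmp22 0.17 and Mbp 0.030. With Mov10 as a covariate Pmp22 was 0.025, Mbp 0.11 and, in S970D against WT, Egr2 0.32. Pmp22 was 0.10 with both libraries left out and 0.10 without the libraries numbered 1. Epha7 in S970D against WT was 0.089 with the trend removed, 0.089 with the block as well and 0.089 with S970A replicate 1 left out as well. In S970D against S970A, Upf2 was 0.054 and Hspa4l 0.050 with the trend removed, and the same 0.054 and 0.050 with the block as well. With S970A replicate 1 left out and the trend removed they were 0.21 and 0.20, Ptar1 was 0.18, Epha7 0.026, Hsph1 0.027 and Rab25 -0.14. The depth of the libraries is unknown, so its limit on low genes could not be given.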

Other observations

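The tests of the main axis by Mov10 level, by a wrong label, with its held-out libraries, and by a shift of the libraries numbered 1, the test of gene order and all values with the trend over GC content and length removed were chosen after the result was seen, and the tests of non-coding genes and microRNA sites before.

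Once the trend over GC content and length was removed from each library, 2 other lists were called in S970D against WT. The NF-kappaB and inflammation list had a median log2 fold change of -0.25 against WT (camera adjusted p = 0.0475) and -0.14 against S970A (0.0354). Immediate early genes, a separate list, had -0.36 in S970D against WT (0.0110) and -0.14 in S970A against WT (0.00528), and were not called in S970D against S970A (-0.24, 0.140). None of these was called before the removal, and each of these calls was lost with an estimated correlation (adjusted p = 0.725, 0.780 and 0.775 with an estimated correlation in S970D against WT, S970D against S970A and S970A against WT). The cytokine gene Il6 was at 4.81 ± 0.28 log2 CPM in WT, 4.29 ± 0.37 in S970A and 3.52 ± 0.34 in S970D, and Nfkb1, a subunit of NF-kappaB, at 5.03 ± 0.15, 4.97 ± 0.17 and 4.42 ± 0.17 (mean ± SD, n = 3).

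S970D libraries and S970A replicate 1 lay together on the first component, which held 64.0% of the variance. It still held 54.3% after the trend over GC content and length was removed, which argues against the trend as fitted as the whole cause. That fit used 1 transcript per gene, so a length or GC bias that it misses stays open. A length bias as a part of the cause may hold. Length and fold change in S970D against WT also went together across 628 genes with no coding sequence (Spearman rho = -0.30, and genes are not independent replicates). The Mov10 level cannot be told apart from the other genes of the axis: its within-group correlation with the score was -0.95 (exact permutation p = 0.00926, 216 permutations; -0.76 without the libraries numbered 1), and 25.8% of genes had one as strong. A wrong label of S970A replicate 1 stays open. That library lay away from S970D in Uba7 (0.031 log2 CPM, against 1.45 to 1.92 in S970D), Duxbl2 (0.29, against -4.09 to -2.20) and Btbd16 (-0.29, against 0.50 to 0.60). These genes were ranked by the F test with that library counted as S970A, so they cannot decide on its label. Other genes were chosen without the library tested, as those that parted S970D from S970A replicates 2 and 3 by over 1. On these S970A replicate 1 lay on the S970A side in 6.43% to 7.77%, not above the range of held-out S970D libraries (6.97% to 20.9%). Held-out S970A replicates 2 and 3 lay there in 85.7% and 87.0%. In the other settings tried, S970A replicate 1 was also not above the highest held-out S970D library. The main axis was not taken out of these genes, so these shares restate the place of S970A replicate 1 on the axis and cannot decide either. The position of S970A replicate 1 on 50 genes off the axis, 0.41, separates nothing, since held-out S970D libraries lay from -0.374 to 0.532. A shift of the libraries numbered 1 also stays open: they scored above the others of their group by 0.361 in WT, 0.675 in S970A and 0.164 in S970D, and of the 27 ways to pick 1 library from each group 9 put all 3 on 1 side of the others (0.333) and 1 puts all 3 above, so the MOV10 form is not the only explanation left.

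S970A lay between WT and S970D in 132 of the 147 genes whose 3 groups did not overlap, and WT lay in the middle in 10, or 6.80%. This order was weaker without S970A replicate 1. Of 771 such genes WT then lay in the middle in 315, 40.9%, S970A in 443, 57.5%, and S970D in 13, where chance gives 33.3% for each. Whether the 2 substitutions move genes to opposite sides of WT cannot be told apart from the place of that library on the first component. Uba7 and Asb2 were among the 10, lower in S970A and higher in S970D than in WT, with limma adjusted p-values of 0.298 and 0.407 between S970D and S970A.

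A hypothesis that S970D alters silencing by microRNAs was tested on 3' untranslated regions of 10816 genes. For 0 of 8 microRNA families did genes with a site differ in S970D against WT from genes with other sites of like GC count, beyond length and GC content. The levels of these microRNAs in the cells were not measured here, so the test does not decide on the hypothesis. The mean residuals lay from -0.04 for miR-30 (adjusted p = 0.169) to 0.00 for let-7 (adjusted p = 0.938) on the log2 scale. The lower level of the let-7 target list was thus not seen across the 337 genes with a let-7 site, beyond length and GC content.

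The authors' deposited table gives a cluster colour to 6419 genes, and 6004 of them changed in S970D against WT with the replicate block. The rule and the data behind these clusters are not given in the sources used here, so they are not taken as independent evidence. In the authors' deposited table the median log2 fold change here was 0.87 for the 2194 blue genes, 0.82 for the 785 brown, -0.84 for the 2956 turquoise and -0.74 for the 484 yellow.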
